A study of Mus musculus with 2 samples.

How the data were processed

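Small RNA sequencing was carried out on J1 mouse embryonic stem cells, an established line of the 129S4/SvJae strain, after 6 h with DMSO or with 1 µM SC1. The medium held 1000 U/mL LIF, per the labels' protocols. Each condition had 1 library.

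For each library the authors deposited a list of distinct sequence tags with raw read counts, and the length of each tag in nt. The listed length equalled the length of the sequence on every line. The counts are whole numbers and were not normalized. The last line of the DMSO list holds only a total of 18870345, which equalled the sum of its counts and was left out. The build mm9 is named in the submitters' processing notes. The adapter, the trimming, the length filter and the aligner are not given in the sources used here.

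The planned comparison was the log2 ratio of each mature miRNA between the libraries, scaled to all reads assigned to mature miRNAs, without a test because there was 1 library per condition. It could not be computed, nor could the planned median ratios of miRNA lists. The DMSO list held tags of 18 to 44 nt and the SC1 list tags of 3 to 17 nt, so the planned window of 18 to 26 nt took in 0 SC1 reads. The SC1 list held 0 reads of 18 nt or more, and the DMSO list 0 reads of 17 nt or less. Each list is therefore described on its own, and its total is that of a length class, not the depth of the library.

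Tags of 15 to 31 nt were matched exactly and in sense to GENCODE M21 mouse transcripts. Coordinates are those of GRCm38, from these matches, and not of mm9. Matches of the reversed tags measured chance. Each tag took the first class it matched, in the order ribosomal RNA genes, Gm42418 or Gm26917, miRNA hairpins, snoRNA or scaRNA, snRNA, mitochondrial tRNA, other small RNA, protein-coding transcripts and other transcripts. Nuclear tRNA and the full ribosomal repeat were not used here, so the ribosomal shares are lower limits. Tags under 15 nt or over 31 nt were not matched.

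The reference had 1174 miRNA genes with a Mir symbol but no mature ends. An arm was therefore defined by its most abundant DMSO tag of 18 to 26 nt, if that tag had 10 reads or more, which departs from the planned annotated ends and lets the DMSO list define what is counted. This gave 590 arms and 483 mature names, called 5p or 3p by their side of the hairpin midpoint. Names follow the gene symbols: miR-124a-3p is the product of Mir124a-1, Mir124a-2 and Mir124a-3. A DMSO tag of 18 to 26 nt was assigned to an arm if it matched the hairpin exactly, started within 2 nt of that tag's start and ended within 4 nt of its end. Tags that fitted several names were split equally. Abundance is given as RPM, reads of a miRNA in each 1000000 reads assigned to mature miRNAs. For the SC1 list, tags of 15 to 17 nt that started within 2 nt of the start of an arm were counted, a measure chosen after seeing the data.

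Intervals are exact (Clopper-Pearson) 95% binomial intervals, and a count of 0 was given the limit of 3 counts. Reads without molecular identifiers are not independent molecules, so intervals and limits cover counting error only. The assignment was run on error-free simulated reads of the same arms, with ends shifted by less than its windows allow. Their assignment was therefore fixed in advance, and random tags hardly ever match a hairpin exactly (0 of 100000 were assigned). The run could show only the effect of tags shared between names. In it 453 of 483 mature names (93.8%) came within 10% of the number drawn. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

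The miRNA lists, the alternatives and the rule for named miRNAs were fixed before the data were examined. The rule takes the 10 most abundant mature miRNAs of each library, the 10 highest and 10 lowest ratios, up to 4 members of each main list at 10 RPM or more, and miR-124-3p. No ratio existed, and the 10 miRNAs with the most short SC1 reads took the place of the 10 most abundant of that library; further members of the other lists were named after their values were seen. Counting miR-92 and miR-18 of the reference as miR-92a and miR-18a of the list was decided after a first pass. The alternatives were other minimum counts and abundances, scaling to all reads, thinning of the DMSO reads to the total of the SC1 list, shared tags left out, only the most abundant tag of each arm, removal of untemplated 3′ A or T, and counts of distinct tags.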

Results

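Small RNAs of J1 mouse embryonic stem cells were sequenced after 6 h with DMSO or with 1 µM SC1 (pluripotin), a small molecule known to inhibit ERK1 and RasGAP and to promote self-renewal. The stated purpose was to find miRNAs regulated by SC1. Each condition had 1 library, so no value has a replicate error. The DMSO list held 18870345 reads in 910008 distinct tags, of which 665655 (73.1%) were seen once. The SC1 list held 1275599 reads in 88867 distinct tags, of which 59609 (67.1%) were seen once.

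The comparison of SC1 with DMSO could not be made for any mature miRNA, because the lists covered different RNA lengths. DMSO tags were 18 to 44 nt long and were most frequent at 22 nt (15.6% of reads). Lengths of 21 to 23 nt, usual for mature miRNAs, held 39.7% of reads. However, 24 nt (12.9%) held more reads than 21 nt (12.4%) or 23 nt (11.8%), and 11.5% of all DMSO reads were assigned to mature miRNAs. SC1 tags were 3 to 17 nt long and were most frequent at 17 nt (42.1% of reads). The lists shared 0 tags and 0 lengths. Within the planned window of 18 to 26 nt, 2167143 DMSO reads and 0 SC1 reads were assigned to mature miRNAs, with arms defined by their most abundant DMSO tag. No miRNA is reported as higher or lower after SC1, and the missing full-length reads are not a measured loss of miRNAs.

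**Figure D1:**
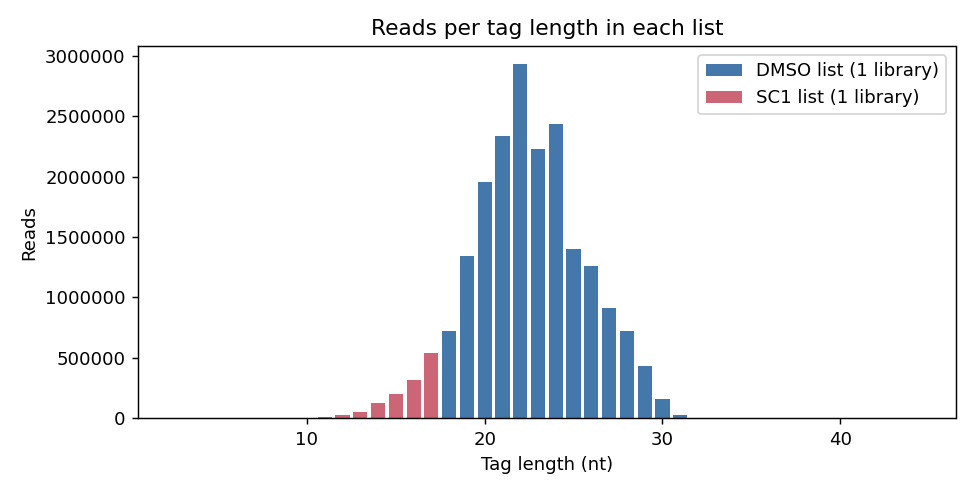
Reads (vertical axis) per tag length (nt, horizontal axis) in the DMSO list and the SC1 list, 1 library each. The bars do not overlap: the SC1 list ends at 17 nt with 537069 reads and the DMSO list begins at 18 nt with 718804 reads.

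In the DMSO library, mature miRNAs took 11.5% of the reads, or 7.35% when only the most abundant tag of each arm was counted and 0.482% by distinct tags. Reads were found for 483 mature miRNAs, 448 of them at 10 RPM or more (252 when scaled to all reads of the list). A miRNA without a tag of 10 reads or more was not counted, and the lowest counted, miR-149-5p, was at 4.61 RPM. The 10 most abundant took 50.5% of the mature miRNA reads. The miR-290-295 cluster, the main miRNA cluster of mouse embryonic stem cells, took 29.0% (interval 28.9 to 29.1) over 14 arms. Its members miR-293-3p and miR-290a-5p led all miRNAs, at 100518 RPM (interval 100118 to 100919) and 95427 RPM (interval 95036 to 95819). Their genes lie on chromosome 7 of GRCm38, Mir293 at 3220343 to 3220422 and Mir290a at 3218626 to 3218708. No other annotated gene overlapped them on their strand, with miRNA genes left out of the search. In the same cluster miR-294-3p was at 25217 RPM and miR-295-3p at 19475 RPM. With only the most abundant tag of each arm, miR-290a-5p was at 63488 RPM and miR-294-3p at 37952 RPM.

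Outside that cluster, miR-140-3p was at 66442 RPM (interval 66111 to 66775), or 31032 RPM with only its most abundant tag. Its gene overlaps an exon of Wwp2 on chromosome 8, at 107551244 to 107551313. miR-103-3p was at 48202 RPM and comes from introns of Pank3 (Mir103-1, chromosome 11, 35782396 to 35782481) and Pank2 (Mir103-2, chromosome 2, 131288052 to 131288137). miR-25-3p, whose gene overlaps an annotated exon of Mcm7 on chromosome 5 at 138165321 to 138165404, was at 45560 RPM. miR-423-5p, from an intron of Nsrp1, was at 37283 RPM and miR-320-3p at 33518 RPM. let-7c-5p was at 28192 RPM and let-7f-5p at 24290 RPM.

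**Figure D2:**
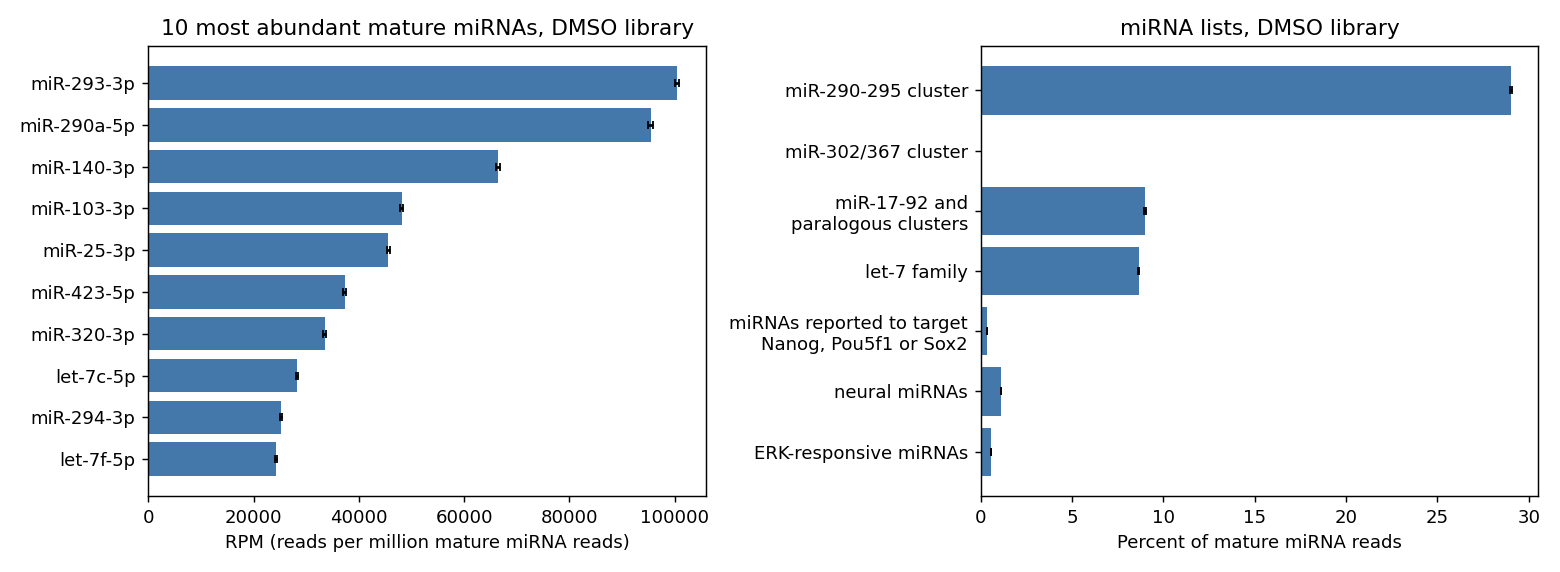
Left, RPM (horizontal axis) of the 10 most abundant mature miRNAs of the DMSO library. Right, percent of mature miRNA reads in each main list; bars are values of 1 library and error bars exact 95% counting intervals. miR-293-3p stands at 100518 RPM and the miR-290-295 cluster at 29.0%.

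The cluster of miR-302 and miR-367, also known from pluripotent cells, held 219 DMSO reads on 3 arms, 0.0101% of the mature miRNA reads (interval 0.00881 to 0.0115). miR-302a-5p was at 67.8 RPM, miR-302d-3p at 21.2 RPM, and miR-302a-3p had 26 reads. The miR-17-92 cluster and its paralogs, known to promote proliferation, took 9.0% over 22 arms, led by miR-25-3p, miR-92-3p at 14764 RPM, miR-363-5p at 8481 RPM and miR-25-5p at 7662 RPM. The let-7 family, which is known to favour differentiation, took 8.64% over 10 arms, with let-7a-5p at 15750 RPM and let-7e-5p at 8242 RPM behind let-7c-5p and let-7f-5p. With only the most abundant tag of each arm the order turned. The let-7 family then took 12.2% and the miR-17-92 cluster and its paralogs 8.52%.

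miRNAs reported to target Nanog, Pou5f1 or Sox2 took 0.34% of the DMSO mature miRNA reads. miR-134-5p was at 1453 RPM, miR-296-3p at 1212 RPM, miR-296-5p at 635 RPM and miR-145a-5p at 54.4 RPM. The lists count both arms of each miRNA, whichever arm a report concerned. Of the 2627 reads of miR-296-3p, 2445 were 1 tag of 18 nt. Neural miRNAs took 1.12%, led by miR-128-3p at 8502 RPM, with miR-219a-3p at 179 RPM and miR-9-5p at 139 RPM. The ERK-responsive list took 0.575%, or 0.299% with only the most abundant tags. In it miR-21a-5p was at 4850 RPM, miR-222-3p at 507 RPM, miR-221-3p at 363 RPM and miR-221-5p at 16.6 RPM.

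The study behind the series is known to follow miR-124-3p. In DMSO it had 4815 reads, 2222 RPM (interval 2160 to 2285), or 3611 RPM after removal of untemplated A or T. Its genes are Mir124a-1 on chromosome 14 (64590657 to 64590741), Mir124a-2 on chromosome 3 (17795662 to 17795770) and Mir124a-3 on chromosome 2 (180894040 to 180894107), each in an exon of a lincRNA. The SC1 list held 8 short reads with its start, a value that cannot be set against the DMSO level.

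Dlk1-Dio3 locus miRNAs, from an imprinted region of chromosome 12, took 7.64% of the DMSO mature miRNA reads over 75 arms, with miR-323-3p at 12002 RPM and miR-433-3p at 8612 RPM. Sfmbt2 locus miRNAs took 1.85%, with miR-669c-5p at 15505 RPM. The miR-183 cluster took 1.06%, the family of miR-34 and miR-449 0.451% and the miR-200 family 0.119%. Among markers of other cell types, the mesenchymal and fibroblast list took 0.259%, with miR-143-3p at 877 RPM, the muscle list 0.159% and the blood list 0.0277%. The liver and gut list took 0.519%, with miR-192-5p at 5060 RPM.

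Other RNA classes were counted in each list. Of the DMSO reads of 18 to 31 nt, 28.6% matched a transcript of the reference, against 0.0351% for reversed tags. Gm42418 or Gm26917, lincRNA genes of chromosome 17 that are known to cover part of the ribosomal RNA repeat, matched 11.6%, and miRNA hairpins also 11.6%. Protein-coding transcripts matched 2.82%, snoRNA or scaRNA 1.24%, ribosomal RNA genes 0.194% and snRNA 0.159%. The most abundant DMSO tag, AGGTGTAGAATAAGTGGGAGGCCC, had 779779 reads (4.13%) and matched no transcript used here.

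The SC1 list held mainly fragments of 15 to 17 nt, 82.7% of its reads. Of these, 6.25% matched Gm42418 or Gm26917, 5.06% miRNA hairpins, 1.36% ribosomal RNA genes and 0.416% snoRNA or scaRNA. By reads the share of Gm42418 or Gm26917 was lower in the SC1 list than in the DMSO list. By distinct tags the order turned, with 2.65% in SC1 and 1.15% in DMSO. The lists hold different tag lengths, so neither order can be read as an effect of SC1. Protein-coding transcripts matched 5.51%, but reversed tags matched them in 3.90% of reads. In all, 97.9% of these reads (interval 97.9 to 98.0) lay inside a DMSO tag, against 0.537% with reversed tags, and 96.5% were the start of one. By distinct tags, a count added after seeing the data, 70.0% lay inside a DMSO tag, against 0.649% of reversed tags, and 54.6% were the start of one. Inside DMSO tags with 10 or more reads lay 94.0% of the 15 to 17 nt reads, but 36.6% of their distinct tags.

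Short tags with the start of a mature miRNA made up 52698 SC1 reads, 5.0% of the 15 to 17 nt reads, over 228 mature names. The share was 2.54% among 17 nt tags alone and 0.839% by distinct tags. miR-293-3p held 26611 of them (50.5%), miR-25-3p 7814 (14.8%), miR-382-5p 4367 (8.29%) and miR-409-3p 3949 (7.49%). miR-382-5p and miR-409-3p belong to the Dlk1-Dio3 locus, where Mir382 lies at 109733771 to 109733846 and Mir409 at 109743158 to 109743236 of chromosome 12, both within the lincRNA gene Mirg. miR-3473b-3p and miR-3473e-5p, which have the same 18 nt tag, followed with 1034.5 and 1018.5 reads after equal splitting. miR-148b-3p had 679 reads, miR-6240-5p 510, miR-431-3p 465 and miR-27a-3p 463, the last split equally with miR-27b-3p. Of these 10 miRNAs, 2 were also among the 10 most abundant of the DMSO list. From their main start, miR-3473e-5p had 1 DMSO read at 19 nt and miR-6240-5p 1 at 20 nt. Both had 0 reads at 21 to 26 nt. Tags that also match other RNA classes were not removed, and whether these fragments come from mature miRNAs was not tested.

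Short reads of the 10 most abundant DMSO miRNAs ranged widely. miR-293-3p, the first in DMSO, also had the most short reads, and miR-25-3p came second in short reads. Of the others, miR-103-3p had 218 short reads after equal splitting, miR-423-5p 16, miR-290a-5p 12, miR-140-3p 10, miR-320-3p 8, miR-294-3p 6, let-7f-5p 4 and let-7c-5p 0.333 after splitting. The miR-290-295 cluster took 51.0% of the short miRNA reads, but 1.05% of the remaining short miRNA reads once those of miR-293-3p were left out. The miR-17-92 cluster and its paralogs took 15.2%, with 7814 of their 8027 reads from miR-25-3p. Dlk1-Dio3 locus miRNAs took 19.1%, or 10045 reads, of which 4367 came from miR-382-5p and 3949 from miR-409-3p. The let-7 family took 0.0171%, and the 3 counted arms of the cluster of miR-302 and miR-367 had 0 reads, which allows up to 0.00569%. miRNAs reported to target Nanog, Pou5f1 or Sox2 took 0.514%, with 264 of their 271 reads from miR-296-3p. The miR-183 cluster took 0.302%, the mesenchymal and fibroblast list 0.093%, neural miRNAs 0.0759% and Sfmbt2 locus miRNAs 0.0645%. The family of miR-34 and miR-449 took 0.0361%, the ERK-responsive list 0.0209%, the miR-200 family and the liver and gut list 0.00949% each, the blood list 0.00569% and the muscle list 0.0019%. The DMSO list held 0 reads of these lengths, so these shares have no DMSO counterpart.

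**Figure D3:**
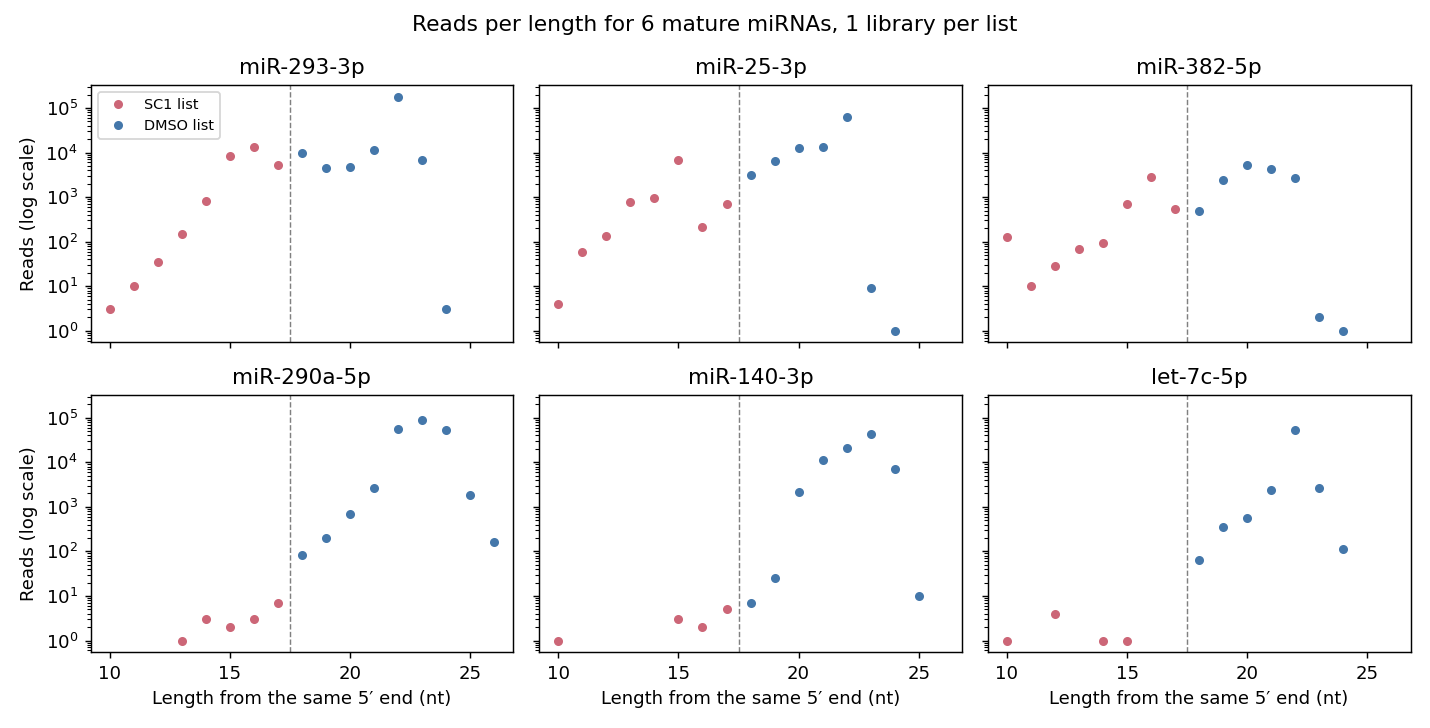
Reads of the exact tag (log scale, vertical axis) per length from the same 5′ end (nt, horizontal axis) for 6 mature miRNAs; lengths to 17 nt are from the SC1 list and longer ones, right of the dashed line, from the DMSO list, and lengths without reads have no point. miR-293-3p had 13062 reads at 16 nt and 179694 at 22 nt, whereas miR-290a-5p had 3 at 16 nt and 88091 at 23 nt.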

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

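All tests below were chosen after the patterns or related values had been seen, except the test of sequencing errors over both TTCAAATC tags, which was set before its result; its split by tag was made afterwards.

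The lists shared 0 tag lengths, and a length filter before deposit may account for this, since the SC1 list ended at its most frequent length, with 42.1% of its reads at 17 nt. Degraded RNA as the whole cause would let the list taper off, which the same share at its last length argues against; degradation together with a filter stays open. The list labelled SC1 could also hold the short reads of the DMSO library: the median log2 ratio of a 17 nt SC1 tag to the 18 nt DMSO tag with the same start was -0.87 over 3054 pairs. This lay just above the adjacent steps, -0.96 (16 to 17 nt, SC1) and -1.12 (18 to 19 nt, DMSO). It lay within the range of all steps measured inside a list, which also included -1.0 (15 to 16 nt, SC1) and -0.54 (19 to 20 nt, DMSO). The quartiles of the 17 to 18 nt step were -2.58 and 1.05, so pairs spread far wider than these medians differ. A separate SC1 library of like depth would give a similar step, so these cannot be told apart, and an effect of SC1 on lengths was not tested.

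Short reads at the start of mature miRNAs, 52698 in the SC1 list, are a signal outside the planned comparison, and 81.1% of them came from miR-293-3p, miR-25-3p, miR-382-5p and miR-409-3p. Tags shared within families do not account for this, since these miRNAs held 86.9% of the reads that fitted 1 name. The 278 miRNAs compared next are not independent replicates. They had 100 or more DMSO reads of 18 nt and 21 to 23 nt together, with shared tags left out. Inside the DMSO list, their 18 nt and 21 to 23 nt reads gave a Spearman rho of 0.351. SC1 short reads followed DMSO 18 nt reads (rho 0.759) more closely than DMSO 21 to 23 nt reads (rho 0.297). The difference was 0.462 (bootstrap interval 0.339 to 0.572). Short fragments that form in both libraries may give this, but cannot be told apart from a single library in both lists. SC1 treatment cannot be told apart from the length class, because the DMSO list has 0 reads of 15 to 17 nt.

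Tags that read TTCAAATCCCGGACGAG apart from the fifth position, counted from 1 at the 5′ end, carried another base there in 9387 of 11633 SC1 reads (80.7%, interval 80.0 to 81.4), also outside the planned comparison, and in 81.1% of 8848 DMSO reads; in the SC1 list A5T made up 48.9%, A5G 28.4% and A5C 3.34%. The error test over this tag and TTCAAATCTCGGTG came out on the side of sequencing errors, because another position of the second tag reached 69.1% in DMSO; there 2659 reads carried G12C, more than the 1190 without a change outside the fifth position. Errors are argued against for the first tag, where the highest other position was 1.27%, and for the second tag in the SC1 list, where it was 1.43% beside 71.8% at the fifth; the G12C reads themselves carried another base at the fifth position in 82.3%. A modified base misread by reverse transcriptase, such as the methylated adenosine known in the T loop of tRNAs, and tRNA gene copies that differ at this base cannot be told apart, as nuclear tRNAs were not used here and the 3 transcripts with any of the tags were of Pyy; no biological explanation by SC1 was tested.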

How the results depend on the processing

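No paired analysis was possible because each condition had 1 library. TMM, size factors, list medians at another minimum and summed list ratios were not run, since no SC1 to DMSO ratio existed. Changes in read shares below exceed counting error, which is not the measure for the number of miRNAs or for shares by distinct tags. The cause of the changes was not tested. The DMSO mature miRNA share (11.5%) was 11.9% and 12.3% with tags of at least 2 and 10 reads, 11.3% without shared tags, 7.35% with only the most abundant tag of each arm, 12.7% after A or T removal and 0.482% by distinct tags. The DMSO miR-290-295 share (29.0%) was 29.1% with tags of at least 10 reads, 29.4% without shared tags, 29.9% with only the most abundant tags and 27.7% after A or T removal. The number of miRNAs at 10 RPM (448) was 243 at 100 RPM and 252 scaled to all reads. The Gm42418 or Gm26917 share was 12.4% (DMSO) and 6.56% (SC1) with tags of at least 10 reads, and 1.15% and 2.65% by distinct tags. The SC1 share of short miRNA starts (5.0%) was 5.40% with tags of at least 10 reads, 4.66% without shared tags and 0.839% by distinct tags; the miR-290-295 part (51.0%) was 51.9% and 54.7% under the first 2 of these. Further settings were chosen after seeing the data. The Gm42418 or Gm26917 share was 10.9% in 18 nt DMSO and 8.27% in 17 nt SC1 tags. In 17 nt tags the short start share was 2.54% and its miR-290-295 part 39.7%. Without miR-293-3p that part was 1.05% of the remaining short miRNA reads. The DMSO miR-17-92 share was 7.20% without miR-92 and miR-18. By distinct tags 70.0% and 54.6% of 15 to 17 nt SC1 tags lay inside or at the start of a DMSO tag. Of 89 other values, mostly of single miRNAs and lists and including the last 3, 48 moved; scaling to all reads, which changes only the unit, is not among them. Under 5 tag rules miR-293-3p led in DMSO, and the 10 most abundant were shared, except that miR-181d-5p replaced let-7f-5p after A or T removal. The order within these 10 was not always kept. Without shared tags, for example, miR-25-3p (46255 RPM) passed miR-103-3p (43745 RPM).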

Other observations

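The arm with more reads differed between members of the miR-290-295 cluster in the DMSO library. Whether these read counts follow the use of the arms in the cells was not tested. miR-291a-5p was at 12681 RPM and miR-291a-3p at 4193 RPM, and miR-291b-5p at 2057 RPM and miR-291b-3p at 444 RPM. By contrast miR-292-3p was at 11794 RPM and miR-292-5p at 5186 RPM, and miR-293-5p was at 6450 RPM. The 3p arm of Mir290a was at 157 RPM. The most abundant DMSO tag of miR-92-3p was 20 nt long with 15730 reads, that of miR-101b-3p 19 nt with 19952 reads and that of miR-323-3p 19 nt with 13855 reads.

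Of the DMSO reads that start like miR-293-3p, 4.41% were 18 nt long, against 0.0411% for miR-290a-5p and 0.00556% for miR-140-3p. The share was 19.5% for miR-409-3p, 3.94% for miR-382-5p and 3.25% for miR-25-3p, the other miRNAs with most short reads in the SC1 list.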
